A study of Mus musculus with 10 samples.

How the data were processed

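Read counts per gene were analysed for 10 mouse retina libraries, 5 vehicle and 5 vigabatrin, grouped by the treatment label. The deposited values are raw read counts per Ensembl gene, made with HTSeq 0.6.1 on genome build mm10 per the submitters' processing notes, which also name DESeq2 and edgeR 3.16.5. The aligner, the annotation release and the strand setting are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. The deposited gene lengths came with the table and served a correction for length and GC content, in which a loess fit (span 0.3) of each library's log2 CPM, centred per gene, was subtracted. Per the labels' protocols, retinas were frozen, RNA was extracted with Qiazol and libraries followed Illumina's standard protocol. The count table held 1 column that matches no sample used here, and it entered no step. Of the table's genes, 97.77% were found in GENCODE M21 and 99.84% of those overlapped its coordinates.

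Counts were filtered with filterByExpr, scaled by TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, limma 3.58.1, R 4.3.3), with group as the only term and Benjamini-Hochberg adjusted p under 0.05 as the threshold. CPM values use the TMM library sizes, and the standard error is the log2 fold change divided by the root of the F statistic. Totals of 36056135 to 54052502 counts per library gave a median standard error of 0.09 on the log2 scale, and the common biological coefficient of variation was 0.191. Pairs of libraries within a group differed well beyond counting noise (chi-square per degree of freedom between 8.54 and 143), so none was counted as repeated sequencing of another. This cannot tell whether libraries share an animal.

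Before the data were examined, 35 gene lists were fixed for retinal cell types, neighbouring tissues and pathways, of which 33 were tested and 2 served as checks of sex and substrain. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, and list means were compared by an exact two-sided permutation test over 252 assignments, whose smallest p is 0.00794. The 4 list tests were each adjusted over the 33 lists. The genes named were also fixed beforehand: the members of GABA metabolism and transport, the 12 genes per direction of largest change past the threshold with a mean CPM of at least 1, the 3 of smallest p per direction, up to 4 of smallest p per list described and, since fewer than 10 genes passed, the 10 of smallest p per direction. Predicted genes and pseudogenes were passed over, 2 of them among the higher genes, and 4 genes that these rules select are not reported here or followed under the alternatives. Gm26917, Yam1, Fabp5, Rdh5, Dusp5, Bdnf, Dusp4, Inhba, Spry2, Nptx2 and Homer1, and the immediate early genes Fos and Egr1, were named after their values were seen.

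On counts simulated from the real means, library sizes and dispersions for this comparison, with 200 of 17435 genes changed, the test recovered 22.4% of genes changed 1.25-fold, 71.6% of those changed 1.5-fold and 89.4% of those changed 2-fold, with 3 false calls. With no gene changed it called 0 genes and camera called 1 of the 33 lists. The genes were simulated independently of each other, so this does not cover lists whose members vary together. In the splits of the real libraries described below, the real grouping aside, camera called a median of 8 lists.

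Alternatives covered normalization (DESeq2 1.42.0 size factors, library size, upper quartile), filters, tools, leaving out each library, the range of the title numbers, a surrogate variable (sva 3.50.0), levels of carried-over tissue and thresholds. Terms for lens and pigment epithelium together, and a fit without the 4 lens-rich libraries, were added after seeing the data. Xist had at most 20 counts and Ddx3y at least 2382 in every library, so no term for sex could be fitted. Nnt, a gene that differs between C57BL/6 substrains, had 509 to 884 counts.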

Results

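Retinal RNA was sequenced from C57BL/6 mice aged 10 to 12 weeks, with 5 libraries from vehicle mice and 5 from mice given vigabatrin at 140 mg/kg/day for 11 days from an osmotic pump under the skin. Vigabatrin is an antiepileptic drug that irreversibly inhibits GABA transaminase, the enzyme that breaks down the transmitter GABA, and loss of visual field is a known adverse effect in patients. The titles of the control libraries call them untreated, whereas their treatment label says vehicle. Libraries are named here by group and by the number in their title. Total counts ranged from 36056135 (vehicle 2345) to 54052502 (vigabatrin 2429) over 35275 genes, of which 17435 were tested. The labels do not say that each library came from a separate animal, so p-values measure the spread between these libraries.

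The comparison asked which retinal transcripts differed after vigabatrin. St8sia2, which encodes a sialyltransferase that adds polysialic acid to the neural cell adhesion molecule, rose from 23.3 ± 0.578 CPM in vehicle to 29.4 ± 0.654 CPM after vigabatrin (SD, n = 5 each). Its log2 fold change was 0.33 with a standard error of 0.04, and all 5 vigabatrin libraries lay above all 5 vehicle libraries (edgeR quasi-likelihood test, adjusted p = 0.0391). St8sia2 (ENSMUSG00000025789) lies on chromosome 7 from 73939119 to 74013682 on the minus strand of mm10. It was the only gene past the threshold: 1 gene was higher and 0 were lower. At an unadjusted p under 0.05 there were 641 higher and 643 lower genes, 1284 in all against 872 expected by chance. Of 100 splits of the 10 libraries into 5 and 5, 16 gave at least as many, the real one included. Most of these 16 divided the libraries rich in lens transcripts unevenly, so that count alone cannot weigh the excess. Among the 47 splits with 2 such libraries on each side, only the real one and 1 other gave at least as many. That other split had 2275 genes and differs from the real one by exchanging vehicle 2345 for vigabatrin 2347. DESeq2's Wald test called 35 genes higher and 49 lower, and limma-voom with quality weights called 3 higher and 0 lower. The call of St8sia2 was lost, with its log2 fold change between 0.32 and 0.34, when any library other than vehicle 2345 was left out (adjusted p between 0.0503 and 0.262). Without vehicle 2345 the same test called 13 genes higher and 26 lower, and without vigabatrin 2347 it called Atf5 and not St8sia2.

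**Figure D1:**
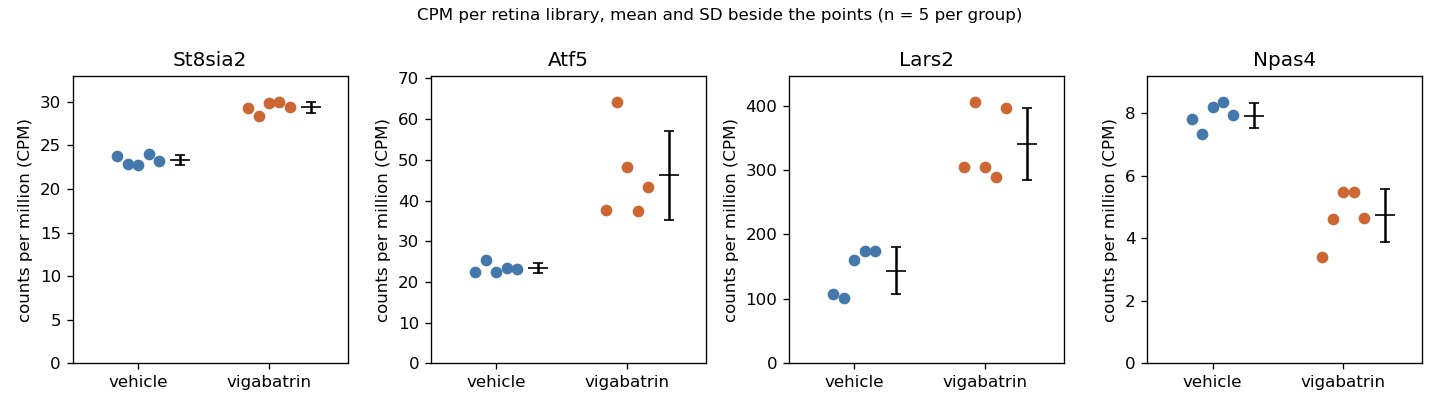
Expression (CPM) of St8sia2, Atf5, Lars2 and Npas4 in each retina library, by group, with the mean and SD (n = 5) beside the points. The vigabatrin libraries of St8sia2 lie between 28.3 and 30.0 CPM and its vehicle libraries between 22.7 and 24.1 CPM, while Atf5, Lars2 and Npas4 did not pass the threshold.

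The other genes of smallest p did not pass the threshold and are given as values. Among those with higher means were Atf5, a transcription factor of the integrated stress response (23.4 against 46.1 CPM, log2 fold change 0.98, SE 0.13, adjusted p = 0.104), and Lars2, the mitochondrial leucyl-tRNA synthetase (144 against 340 CPM, 1.24, SE 0.17, adjusted p = 0.104). The log2 fold changes of the others were 0.34 for Tril, 0.23 for Lphn3, a latrophilin, 0.24 for Pkia, 0.27 for Rhobtb3, 0.23 for Syt7, a synaptotagmin, 0.25 for C1ql1 and 0.25 for Nlgn1, a neuroligin. Among those with lower means, Npas4, a transcription factor induced by neuronal activity, had 7.92 CPM in vehicle and 4.73 CPM after vigabatrin (log2 fold change -0.74, SE 0.12, adjusted p = 0.18). Rem2, a small GTPase, had -0.73, Vgf, a secreted neuropeptide precursor, -0.75, and Etv4, a transcription factor, -0.89. Spc25 had -0.40, Ebpl -0.46, Gnb5 -0.35, Acsl3 -0.33, Ubap1l -0.29 and Sag, the rod arrestin, -0.21. With the title number range as a term, which leaves vehicle 2345 as the comparison for the vigabatrin libraries, Vgf had -0.328, Etv4 -0.299, Ebpl -0.081, Gnb5 -0.076, Acsl3 -0.047 and Ubap1l -0.109, while Atf5 had 0.991, Lars2 0.966, Npas4 -0.744 and Rem2 -0.626. The vehicle and vigabatrin libraries of Atf5, Lars2, Npas4 and Rem2 did not overlap, as was the case for 258 tested genes in all (1.48%, where chance gives 0.794%).

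Genes of GABA metabolism and transport, the pathway of the drug's target, did not pass the test. Abat, which encodes GABA transaminase, measured 132 ± 5.57 CPM in vehicle and 136 ± 4.64 CPM after vigabatrin (SD, n = 5 each; log2 fold change 0.04, SE 0.04, adjusted p = 0.85). Of the 11 members tested, 0 passed over all genes and 0 when adjusted over the list alone. The 7 with higher means included Aldh5a1, succinate semialdehyde dehydrogenase, at 0.11, the transporters Slc6a11 at 0.11 and Slc6a12 at 0.04, the vesicular transporter Slc32a1 at 0.04 and the decarboxylase Gad2 at 0.07. Lower means were found for Gad1 at -0.03 (SE 0.05), Slc6a13 at -0.67 (SE 0.48), Adhfe1 at -0.12 and Akr7a5 at -0.04. Without vehicle 835 Slc6a13 measured -0.271 and Adhfe1 -0.005, and without vehicle 1582 and vigabatrin 2349 Adhfe1 measured -0.049 and -0.018. Gad1 measured -0.008 without vehicle 832 or 2345, and Akr7a5 -0.014 and -0.008 without vehicle 1580 and vigabatrin 2428. Of the higher ones, Slc6a12 measured 0.001 without vigabatrin 2347, Slc32a1 0.015 without vehicle 1582 and Gad2 0.023 without vigabatrin 2349. The list's median log2 fold change was 0.04, whereas its mean log2 CPM differed by -0.03, and camera gave an adjusted p of 0.331 (0.272 as the unadjusted p with an estimated correlation). Among 19 GABA receptor genes, 13 had higher and 6 lower means. Gabrr2, a rho subunit found in the retina, measured -0.24 (SE 0.06) and was the only member called when adjusted over the list alone (1 gene, against 0 over all genes). The list's mean log2 CPM was higher by 0.065 after vigabatrin, with an exact two-sided permutation p of 0.0159 that did not hold after adjustment over the 33 lists (0.262). Camera gave an adjusted p of 0.207. With the title number range as a term the median log2 fold change of the GABA receptor list was 0.003, from 0.064, and Gabrr2 measured -0.04.

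Immediate early genes, which neurons transcribe within minutes of activity, fell as a group, with all 20 tested members lower and a median log2 fold change of -0.44 (camera with a preset correlation, adjusted p = 3.67e-10). With an estimated correlation the list had p = 0.0176 and adjusted p = 0.329, so that call was lost. The mean log2 CPM of the list was 3.50 ± 0.276 in vehicle and 3.01 ± 0.219 after vigabatrin (SD, n = 5 each; exact permutation p = 0.0238, adjusted 0.262). Npas4, Fosb, Egr3 and Atf3 were called when adjusted over the list alone (4 genes, against 0 over all genes), with log2 fold changes of -0.74, -0.64, -1.02 and -0.32. Fos measured -0.77 (SE 0.31) and Egr1 -1.04 (SE 0.58), neither called. The vehicle library with the highest list mean, 3.89, was vehicle 835, which also held the most transcripts of retinal pigment epithelium. Without vehicle 835 the median was -0.29, and without the 4 libraries rich in lens transcripts, an alternative added after seeing the data, it was -0.22. With the title number range as a term, where vehicle 2345 alone stands for vehicle beside the vigabatrin libraries, the median was -0.533.

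**Figure D2:**
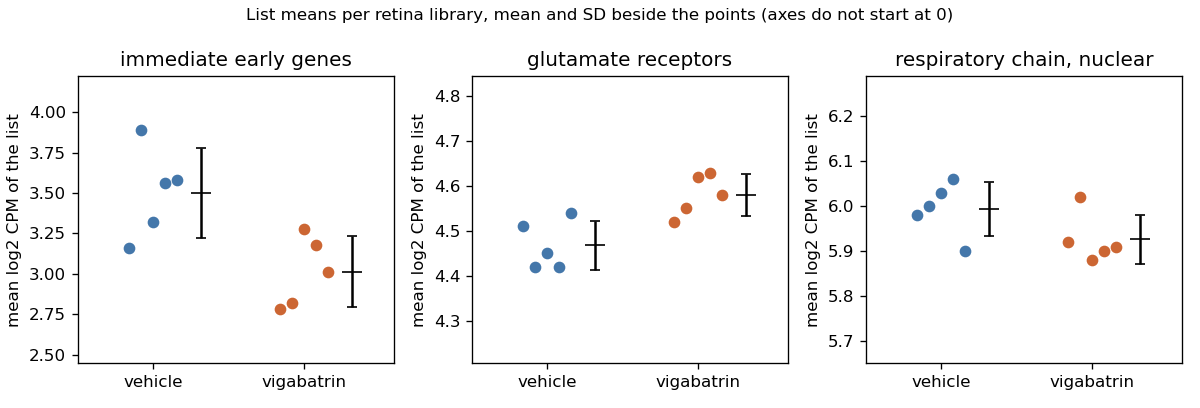
Mean log2 CPM of 3 gene lists in each retina library, by group, with the mean and SD (n = 5) beside the points; the axes do not start at 0. The immediate early genes averaged 3.50 in vehicle and 3.01 after vigabatrin, and the glutamate receptors 4.47 and 4.58.

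Glutamate receptor genes rose as a group, with 23 of 25 tested members higher and a median log2 fold change of 0.10 (camera, adjusted p = 2.52e-05). The unadjusted p was 0.0519 with an estimated correlation and the exact permutation p of the list mean was 0.0159 (adjusted 0.262), so the call rests on the preset correlation. The metabotropic receptor genes Grm2 and Grm3 measured 0.29 and 0.41 and the NMDA receptor gene Grin2b 0.12, with 0 members called over all genes and 0 adjusted over the list alone. Nuclear genes of the respiratory chain fell together by small amounts, with 50 of 53 lower and a median of -0.06 (camera, adjusted p = 3.25e-08). With an estimated correlation p = 0.164, and the exact permutation p of the list mean was 0.119. The median was -0.031 without the 4 lens-rich libraries (adjusted p = 0.0279) and -0.036 without vehicle 1580 and 1582 (0.00669), where that of the glutamate receptors was 0.061 (0.00318). Cycs, Cox5a, Cox6c and Sdhc measured -0.14, -0.14, -0.17 and -0.08, and 0 members were called either way. Ribosomal protein genes fell in the same test (42 of 51 lower, median -0.03, adjusted p = 0.0258), with p = 0.603 with an estimated correlation and an exact permutation p of 0.516 for the list mean. Without vehicle 835 their median was 0.002 and the adjusted p 0.797, and the call was also lost without vehicle 1582 (median -0.017, adjusted p = 0.365) or vigabatrin 2349 (-0.016, 0.352), 2428 (-0.006, 0.528) or 2429 (-0.029, 0.0621). The median was -0.051, -0.05 and -0.054 without vehicle 832, 1580 and 2345 and -0.075 without vigabatrin 2344. When each library's trend on gene length and GC content was removed, a correction chosen after seeing the data, the median difference in log2 CPM of the ribosomal protein genes shrank from -0.032 to -0.012 while its SD over members was 0.045 before and 0.044 after, and the call ended (adjusted p = 0.416). Stress response genes fell as well (17 of 20 lower, median -0.07, adjusted p = 0.00546), with p = 0.0199 and adjusted p = 0.329 with an estimated correlation. The exact permutation p of their list mean was 0.381, and without vehicle 2345 their median was -0.117. Atf4 measured -0.24, Chac1 -0.45, Hspa5 -0.13 and Trib3 -0.24, with 0 called over all genes or adjusted over the list alone. With the title number range as a term the medians were 0.034 for glutamate receptors, 0.026 for the respiratory chain and -0.032 for stress response genes, each with an adjusted p of 0.408.

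Rod genes fell by a small amount, with 16 of 20 lower and a median of -0.07 (camera, adjusted p = 0.0032). With an estimated correlation p = 0.213, and the exact permutation p of the list mean was 0.111. Without vehicle 1580 the median was -0.044 (adjusted p = 0.0276). Sag was called when adjusted over the list alone (3969 ± 190 CPM in vehicle, 3433 ± 150 CPM after vigabatrin; SD, n = 5 each), against 0 genes over all genes, while Nr2e3, Pde6a and Cnga1 measured -0.34, -0.08 and -0.08. With the title number range as a term the median of the rod list was -0.072, from -0.073, while Sag measured -0.119 and Nr2e3 -0.08. Without the 4 lens-rich libraries Nr2e3 measured -0.125. Genes of the retinal pigment epithelium and choroid, tissue behind the retina, were lower (14 of 16, median -1.07, camera adjusted p = 0.00705), with p = 0.323 with an estimated correlation. Visual cycle genes, which share Lrat, Rgr, Rpe65 and Rdh5 with that list, were also lower (12 of 14, median -0.09, adjusted p = 0.0409; p = 0.107 with an estimated correlation). The 4 shared genes measured -3.06, -2.42, -2.86 and -0.935 with standard errors of 0.97, 0.94, 1.13 and 0.47. Of 9 cornea genes fixed, 6 were tested and all 6 were lower (median -1.47, camera adjusted p = 0.00705, p = 0.156 with an estimated correlation). Krt5, Krt12 and Krt15 were called when adjusted over the list alone, against 0 over all genes. They were scarce and variable, at 1.72 ± 1.69, 0.54 ± 0.458 and 2.54 ± 3.14 CPM in vehicle. After vigabatrin they had 0.359 ± 0.223, 0.188 ± 0.118 and 0.463 ± 0.22 CPM (SD, n = 5 each). With the title number range as a term these 3 measured 0.022, -0.406 and 1.484, and the cornea median was 1.111. The exact permutation p of the list mean was 0.357 for pigment epithelium and choroid, 0.159 for the visual cycle and 0.198 for cornea. The amount of carried-over tissue differed between libraries: summed pigment epithelium and choroid transcripts reached 1722 CPM in vehicle 835, 762 in vigabatrin 2344 and 579 in vehicle 1582. Without vehicle 835 the median of the pigment epithelium list was -0.304 and its call was lost (adjusted p = 0.316). That call was also lost without vehicle 832 (median -1.224, adjusted p = 0.0527) or vigabatrin 2349 (-0.787, 0.149) or 2428 (-0.784, 0.0739), and without vigabatrin 2344 the median was -2.052. The call of the cornea list was lost without vehicle 832 (-1.062, 0.0527) or 835 (-1.407, 0.113) or vigabatrin 2347 (-1.211, 0.0558) or 2349 (-1.149, 0.0572). That of the visual cycle was lost with medians between -0.096 and -0.074, close to the -0.09 of all libraries, without vehicle 832 (0.21) or 2345 (0.0934) or vigabatrin 2344 (0.09), 2349 (0.0811), 2428 (0.112) or 2429 (0.0621), and without vehicle 835 its median was -0.15 and it was called (0.0249). The visual cycle call also ended after the correction for gene length and GC content (adjusted p = 0.076), with a median difference of -0.071 from -0.083 and an SD over members of 0.776 from 0.771. Without vehicle 832 and 835 the medians were 0.065 for pigment epithelium and choroid, 0.003 for the visual cycle and -0.276 for cornea, none of them called (adjusted p of 0.949, 0.267 and 0.473). Lens transcripts took 1.95% and 1.30% of all counts in vehicle 835 and 1582 and 2.01% and 1.78% in vigabatrin 2344 and 2429, against at most 0.125% elsewhere. All 20 lens genes had positive fitted log2 fold changes (median 0.35), while the list mean differed by -0.07 and camera's direction was down (adjusted p = 0.882).

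**Figure D3:**
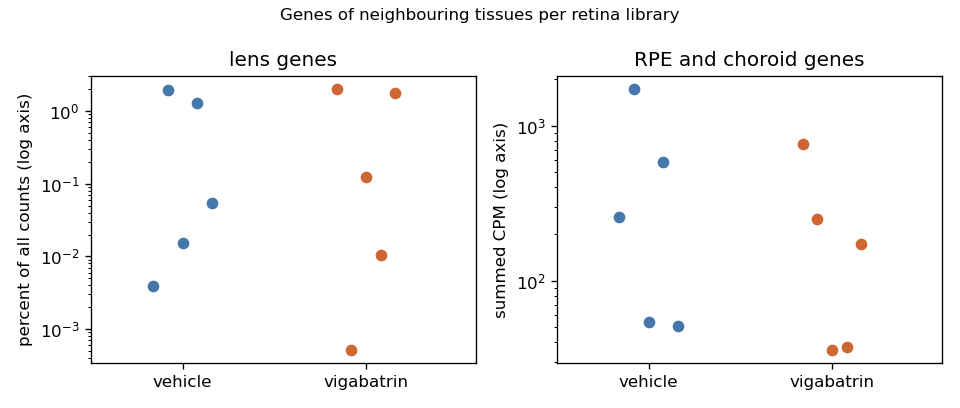
Lens transcripts as a percent of all counts and summed CPM of retinal pigment epithelium (RPE) and choroid genes in each retina library, by group, on log axes. Lens transcripts exceed 1% in 2 vehicle and 2 vigabatrin libraries, and the highest pigment epithelium and choroid sum, 1722 CPM, is in vehicle 835.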

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

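The tests of carried-over tissue and of the title numbers were chosen after the results were seen, as were the resampled interval, without which length and GC content would have been argued against for the glutamate receptors, and a spread condition on the mitochondrial gene medians that altered no outcome; the other tests in this part were written down before they were run, those on activity, Lars2 and length and GC content after the patterns themselves had been seen. Of 136 groups of 5 libraries examined, 8 held a library far from the other 4, where chance gives about 6.8, or 1 in 20. Vehicle 2345 was low for Ebpl (75.4 CPM, others 99.5 to 108), Vgf (57 CPM, others 79.0 to 84.3) and Acsl3 (235 CPM, others 293 to 304). Vehicle 835 was high for Abat at 142 CPM, against 129 to 131. Vigabatrin 2347 was low for Lphn3 at 38.1 CPM, against 40.5 to 41.0, and high for the mean of the nuclear respiratory chain genes at 6.02 log2 CPM, against 5.88 to 5.92. Vigabatrin 2349 was low for Slc6a13 at 3.41 CPM, against 12.5 to 19.3, and vehicle 832 low for the microglia list at 1.62 log2 CPM, against 1.70 to 1.73.

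Chance was not excluded for the number of genes or of lists. The real grouping called 1 gene, and 6 of 100 splits of the 10 libraries into 5 and 5, drawn from 126, called at least as many, with 783 genes in the highest other split. The 5 other splits were those drawn that put the 4 lens-rich libraries on the same side, and they called 112 to 783 genes, which points to lens tissue as a structure of these samples. Among the 47 splits with 2 lens-rich libraries on each side, only the real grouping called a gene. Camera called 9 lists in the real grouping, and 39 of 100 splits called at least as many, up to 18 in another split; of the 47 balanced splits 5 did, the real one included. The immediate early genes reached as small an adjusted p in 5 of 100 splits, the real one included.

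The immediate early genes were lower after vigabatrin. The values argue against carried-over lens and pigment epithelium as the whole cause: with both levels as terms the median log2 fold change was -0.37, from -0.44. The median was -0.22 without the 4 lens-rich libraries and -0.29 without vehicle 835, so a partial contribution of such tissue stays open. A cohort shared by title numbers cannot be told apart from the treatment, because vehicle 2345 is the only vehicle library numbered like the treated ones; its list mean lay 0.30 above the highest vigabatrin library, and with the title range as a term the list stayed lower (median -0.53), both of which rest on that 1 library. Lower activity-driven transcription is a candidate explanation: of 17 further activity-regulated genes, listed without Rem2, Vgf and Etv4 whose values had been seen, 13 were lower and 4 higher. Dusp5, Bdnf and Dusp4 had the smallest p among them, with log2 fold changes of -0.325, -0.364 and -0.345. The 4 higher were Inhba at 0.14, Spry2 at 0.088, Nptx2 at 0.026 and Homer1 at 0.021. These 17 genes were not followed with the title range as a term or without the lens-rich libraries. The median of the 17 was -0.16 (camera p = 0.000546, p = 0.0547 with an estimated correlation, exact permutation p = 0.167). The time from death to freezing, which can also move these genes, was not tested.

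Lars2 was higher beside Gm26917 (log2 fold change 1.37, 4.80 against 12.4 CPM) and Yam1 (869 against 1995 CPM), transcripts beside and over an annotated ribosomal RNA gene on chromosome 17. Reads of ribosomal RNA counted for these genes stay open: Lars2 shared 0 stretches of 25 bases with the annotated ribosomal RNA transcripts, but the longest nuclear one has 1849 bases and the large-subunit RNA was not among those searched, so the search, judged void after its result was seen, decides nothing. A mitochondrial stress response, which might raise Lars2 with Atf5, was argued against by the median of 11 mitochondrial chaperone and protease genes (-0.049) and of 16 other mitochondrial tRNA synthetase genes (0.007). A direct effect of the drug on these transcripts was not tested.

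Glutamate receptors were higher and respiratory chain genes lower. Gene length and GC content could account for part of both: after each library's trend was removed, the median difference in log2 CPM was 0.08 for glutamate receptors and -0.043 for the respiratory chain. The receptors kept 78.6% of their difference (57.1% to 87.4% over resampled members) and the respiratory chain 71.6% (52.4% to 89.4%). The intervals span the bound set beforehand, so a partial contribution stays open, and a treatment effect on these groups was not tested apart from it.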

How the results depend on the processing

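All fits were planned other than the 2 named as added and the correction for length and GC content, which was chosen after the data were seen. The higher count, 1 in the main analysis, was 0 by library size, with no filter, with robust edgeR, against a fold change of 1.2, with title range, pigment epithelium or lens as a term, and without vehicle 832 and 835 or 1580 and 1582. DESeq2's Wald test gave 35 higher and 49 lower, limma-voom 3 higher, and 1 surrogate variable 4 higher and 1 lower. Of the added fits, 2 tissue terms gave 2 (Atf5, Fabp5) and leaving out the 4 lens-rich libraries 0. Leaving out each library gave 0 to 13 higher and 0 to 26 lower, the highest without vehicle 2345. The number of lists called, counted over all lists tested, was 9 in the main analysis. It was 5 with the title range, without vehicle 832 and 835 and with the pigment epithelium term. Of the 9, only rods and immediate early genes stayed called with the title range. Calls in that fit use the preset correlation and rest on vehicle 2345 alone for vehicle. The 5 lists of that fit thus include others that were not called in the main analysis. The number was 0 with an estimated correlation or with fry's test for 1 direction. On leaving out each library it was 5 to 10, the lowest without vigabatrin 2349. It was 10 with the lens term and, of the added fits, 6 with 2 tissue terms and 13 without the lens-rich libraries. After the correction for length and GC content 7 stayed called. Fry's test for change in either direction called 2 lists, amacrine cells (0.000131) and immediate early genes (0.0231). A term for sex was not run, since it did not vary. The cause was not tested.

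The immediate early genes stayed below 0 in all 23 alternatives (medians -0.53 to -0.22). Camera with an estimated correlation and fry are among these but reuse the main fold changes, so their median could not differ, and in both the call was lost. Of 79 named genes followed 64 kept their direction throughout, and 21 of 2033 values reversed. The title range reversed 12 of the 79 and left 36 others at under 0.5 of their value, among them Mal at -0.035, Kdr 0.031, Gabrr2 -0.04 and Glul -0.025. Slc6a12 was -0.027, -0.005 and -0.006 without vehicle 832, vehicle 2345 and vigabatrin 2429, and Gad1 0.005 without vigabatrin 2344; over all libraries left out in turn they ranged from -0.027 to 0.086 and from -0.046 to 0.005, and ribosomal proteins from -0.075 to 0.002. With the title range Adhfe1 was 0.51, Car14 0.16, Ly6c1 0.03, Flt1 0.028, Slc16a8 0.12, Rpe65 0.15, Krt5 0.022, Krt15 1.48, Krt13 0.74, Mog -0.046, Gabrr3 -0.039 and Stra6 0.18, and the lists pigment epithelium 0.31, cornea 1.11, respiratory chain 0.026 and ribosomal proteins 0.048. Without vehicle 832 and 835 Rgr was 0.18, Rpe65 0.38, Krt15 0.34, pigment epithelium 0.065 and visual cycle 0.003. Adhfe1 was 0.046 with the pigment epithelium term and 0.034 with 2 tissue terms, and ribosomal proteins were 0.02, 0.01 and, without vehicle 835, 0.002. The cause was not tested.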

Other observations

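Several groups not described above held a gene called when adjusted over the list alone, none of them called over all genes. Among circadian clock genes, Dbp, an output transcription factor of the clock, had 120 CPM in vehicle and 144 CPM after vigabatrin (log2 fold change 0.27, SE 0.06), while Hlf measured 0.13 and Arntl -0.11, and camera gave an adjusted p of 0.114 for the list. Among amacrine cell genes, Tfap2b measured 0.20 (SE 0.04), Chat 0.19, Slc17a8 0.17 and Sst, somatostatin, -0.94 (SE 0.28). These went both ways, with 11 of 18 higher, and fry's test for change in either direction gave an adjusted p of 0.000131. That test was not run on the splits of the libraries. For a shift in 1 direction, camera gave the amacrine list an adjusted p of 0.251 (0.744 with an estimated correlation). The exact permutation test of its mean gave 0.865 after adjustment. In the vascular list Kdr, a receptor of vascular endothelial growth factor, measured 0.45 (SE 0.11) and Ly6c1 -0.51 (SE 0.15), and with the title number range as a term 0.031 and 0.03. With that term Dbp measured 0.157, Hlf 0.031, Tfap2b 0.123, Slc17a8 0.072 and Sst -0.279.

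Among other cell types, Guca1a of the cone list measured -0.33 (SE 0.08) and Mal of the myelin list -1.29 (SE 0.30), each called over its list alone. With the title number range as a term Mal measured -0.035. Bipolar, ganglion and Müller glia lists had medians of 0.03, 0.03 and 0.05, and microglia and gliosis lists -0.07 and -0.29, none past the threshold in camera (adjusted p of 0.251, 0.3, 0.464, 0.479 and 0.207). Sox9, a Müller glia transcription factor, measured 0.41 (SE 0.12) and Glul, glutamine synthetase, -0.14 (SE 0.05), neither called, and with the title number range as a term they measured 0.214 and -0.025.

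A hypothesis on vehicle 2345 was formed and tested after the data were seen. On 596 genes chosen at p under 0.01 without it, it lay at 0.877 on a scale from the other vehicle libraries (0) to the vigabatrin libraries (1). Because the genes were chosen for a difference between the remaining libraries, a left-out library is not expected at 0. The other 4 vehicle libraries, left out in the same way on 230 to 414 genes chosen with vehicle 2345 among vehicle, lay at 0.326, 0.167, 0.436 and 0.264. Vehicle 2345 may share a cohort with the treated libraries, whose title numbers are close to its own. However, 1 library of 5 has to lie furthest and its gap to the next was below the limit for a far library, so this cannot be told apart from chance.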
